A study of Mus musculus with 14 samples.

How the data were processed

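Gene counts came from live GFP-positive cells, described by the submitters as adult-born granule cells, sorted from the hippocampus of C57BL/6 mice at day 14. Each sample held 800 to 1000 cells, and SMART-Seq v4 cDNA was made from polyadenylated RNA. The table deposited by the authors held raw counts per gene for 14 libraries and 43346 genes, without normalisation, as its whole-number values show. Per the submitters' processing notes the tools were Bowtie2, featureCounts, Subread, R 4.1.1 and edgeR with the genome build hg38, without a role or order for each. Every gene identifier in the table was a mouse Ensembl identifier, so the human build hg38 does not match the table. The annotation release, the strand setting, the rule for reads with several matches and any read filter are not given in the sources used here. Gene symbols and positions were taken from GENCODE M21 on GRCm38 by identifier without version, which matched 42462 identifiers (98%) and left 884 without a symbol.

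Libraries were grouped by their titles into CAG-GFP Sham, CAG-GFP Pilo, DREADD Sham and DREADD Pilo. Total counts ran from 10613291 to 38614639 per library, and a gene without counts in a group was set to 3 counts over that group for a lower bound of its fold. Ratios with 1 to 3 counts in a group carry a 95% exact counting interval. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Levels are given as counts scaled by library total and TMM factor (CPM), with means and SD over the libraries of a group.

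Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter and the quasi-likelihood F-test in 1 fit of all 14 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 18676 genes. The 6 comparisons were CAG-GFP Pilo against CAG-GFP Sham, DREADD Sham against CAG-GFP Sham, DREADD Pilo against CAG-GFP Sham, DREADD Pilo against CAG-GFP Pilo, DREADD Pilo against DREADD Sham, and the interaction of the last with the first. The biological coefficient of variation was 1.47 over all libraries, 1.01 in CAG-GFP Sham, 1.81 in CAG-GFP Pilo, 1.57 in DREADD Sham and 1.16 in DREADD Pilo. No pair of libraries of a group agreed within sampling noise.

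Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and adjustment over 29 lists. Each was repeated with a correlation estimated from the data. List members were also tested with adjustment over the list alone. The lists, with the members tested, were DNA replication and S phase (30), mitosis (30), neural stem cell (23), neuroblast and immature neuron (22), mature granule cell (25), immediate early genes (25), late activity-regulated genes (25), migration and axon guidance (32), extracellular matrix and metalloproteinases (35), glutamate receptors (23), GABA receptors and chloride transport (19), voltage-gated and HCN channels (35), Gi signalling and GIRK channels (27), synaptic vesicle and release (27), oxidative phosphorylation (32), interferon and antigen presentation (25), p53 and integrated stress response (24), heat shock (15) and cholesterol synthesis (21). The remaining lists held markers of microglia (15), astrocytes (14), oligodendrocytes (13), oligodendrocyte precursors (9), endothelium (14), pericytes and smooth muscle (10), interneurons (10), CA pyramidal neurons (12), ependyma and choroid plexus (11) and blood cells (9). Some genes stand on more than 1 list, and neural stem cell genes such as Fabp7 and Slc1a3 are also expressed by astrocytes. A list's median is the median over members of the difference in mean log2 CPM.

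The CPM of the 10 marker lists was also summed per library and compared by an exact two-sided permutation test, adjusted over the 10 lists. With 4 against 3 libraries there are 35 splits and the smallest p is 0.0286; with 3 against 3 the smallest p is 0.1. Rrm2 and Timp3 were tested in the same way on log2 CPM, with adjustment over 10 tests.

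The groups, tests, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule took Rrm2 and Timp3, then per comparison, among genes past the test with a mean of at least 5 CPM in the higher group, libraries that did not overlap between the groups and no predicted name, the 8 largest rises and the 8 largest falls. It added up to 3 members past the test from each list and up to 2 others with the smallest p, dropped the condition on overlap for the interaction, and took the 6 genes with the smallest p where fewer than 4 genes passed. After the values were seen, the members named without passing over all genes were narrowed to those past 0.05 adjusted over the list alone. This favours genes that held across settings, so counts of stable named genes do not stand for unselected genes. Some genes that the rule names are not reported here.

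The alternative settings fixed then were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of 5 CPM in at least 3 libraries, only the compared groups, the replicate number as a block, the naming style of the libraries as a covariate, CAG-GFP Pilo without the libraries of each naming style, a threshold of 0.10, a threshold of 0.05 with a log2 change of at least 1, and each library left out in turn. Chosen after seeing the data were library set as a covariate, comparison within 1 library set, CAG-GFP Pilo 4 and DREADD Pilo 3 left out together, and CAG-GFP Sham summed to 1 sample. Also chosen after seeing the data were the library sets themselves, their pseudogene share, thinning of counts to equal depth, the choice of genes within each divided part of CAG-GFP Pilo, the permutation tests of Rrm2 and Timp3, group means, bounds and ratios without each library, and the check of lists under other size factors.

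The tests were checked on simulated counts for 18676 genes with the measured spread, with 50 genes changed per fold. Each gene was drawn on its own, without correlation between genes. The check of camera therefore cannot show whether its preset correlation suits these data. For CAG-GFP Pilo against CAG-GFP Sham, edgeR recovered 0% of 2-fold, 0% of 8-fold, 22% of 32-fold and 40% of 128-fold changes. For DREADD Pilo against CAG-GFP Pilo these shares were 0%, 4%, 18% and 34%, for DREADD Pilo against DREADD Sham 0%, 0%, 14% and 42%, and for the interaction 0%, 0%, 0% and 4%. For DREADD Sham against CAG-GFP Sham they were 0%, 2%, 26% and 44%, and for DREADD Pilo against CAG-GFP Sham 0%, 0%, 20% and 40%. With the mitosis list raised 4-fold, camera gave an adjusted p of 0.00624 for CAG-GFP Pilo against CAG-GFP Sham, 0.0325 for DREADD Pilo against CAG-GFP Pilo, 0.00768 for DREADD Pilo against DREADD Sham and 0.011 for DREADD Pilo against CAG-GFP Sham, and missed it for DREADD Sham against CAG-GFP Sham (0.101) and for the interaction (0.0971).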

Results

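Gene counts were analysed from 14 RNA libraries of sorted cells, described as adult-born granule cells. Such cells are the neurons that the dentate gyrus of the hippocampus adds in adult life. The cells were sorted as live GFP-positive cells from C57BL/6 mice at day 14, with 800 to 1000 cells per sample, and their polyadenylated RNA was amplified with SMART-Seq v4, a full-length cDNA method for small inputs. The cells expressed GFP from the CAG promoter or a DREADD with GFP, a designer receptor activated by clozapine-N-oxide (CNO) that the labels use for silencing. Mice received pilocarpine at 300 mg/kg, a muscarinic agonist that sets off status epilepticus, or were sham controls, and every group received CNO. CAG-GFP Sham held 3 libraries, CAG-GFP Pilo 4, DREADD Sham 4 and DREADD Pilo 3. The series title names Rrm2 and Timp3 in neurogenesis and neuronal migration following seizures. Nothing in the labels states that the libraries came from separate animals, so p-values measure only the spread between these libraries. Markers of other cell types were abundant. Summed astrocyte markers averaged 25100 CPM in CAG-GFP Sham, against 964 CPM for mature granule cell genes. Oligodendrocyte markers averaged 28200 CPM in DREADD Sham, against 1650 CPM for mature granule cell genes. In DREADD Pilo these were 21800 CPM (426 to 45000 by library) and 680 CPM, and in CAG-GFP Pilo 20300 (1420 to 38700) and 3250 CPM. The lists hold different genes, so these sums do not give cell shares.

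Total counts ranged from 10613291 in CAG-GFP Pilo 2 to 38614639 in CAG-GFP Pilo 4, and the number of genes detected from 9372 in CAG-GFP Pilo 4 to 20863 in CAG-GFP Pilo 3. The CAG-GFP Sham libraries held 27965232 to 28432365 counts, the DREADD Sham libraries 15261512 to 33210468 and the DREADD Pilo libraries 12562178 to 18368478. The 3 CAG-GFP Sham libraries resembled each other more (log2 CPM correlation across genes 0.863 to 0.868) than CAG-GFP Pilo (0.517 to 0.738), DREADD Sham (0.501 to 0.796) or DREADD Pilo libraries (0.594 to 0.773). Genes are not independent replicates. Mitochondrial genes took 12% ± 0.635 of counts in CAG-GFP Sham (SD, n = 3), 7.73% ± 6.45 in CAG-GFP Pilo (SD, n = 4), 3.44% ± 1.33 in DREADD Sham (SD, n = 4) and 11% ± 12.9 in DREADD Pilo (SD, n = 3), with 25.8% in DREADD Pilo 3.

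The libraries fell into 2 sets that crossed the groups. Set 1 held all CAG-GFP Sham libraries, CAG-GFP Pilo 3 and 4, and DREADD Sham 1 and 2, with 23965564 to 38614639 counts. Set 2 held CAG-GFP Pilo 1 and 2, DREADD Sham 3 and 4, and all DREADD Pilo libraries, with 10613291 to 19595245 counts. Pseudogenes took 0.117% to 0.2% of counts in set 1 and 4.33% to 8.12% in set 2. Below, values within a set stand beside the pooled ones for Rrm2, Timp3, the genes that open each comparison, list calls that a set ended and counts of called genes; no set held both CAG-GFP Sham and DREADD Pilo.

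**Figure D1:**
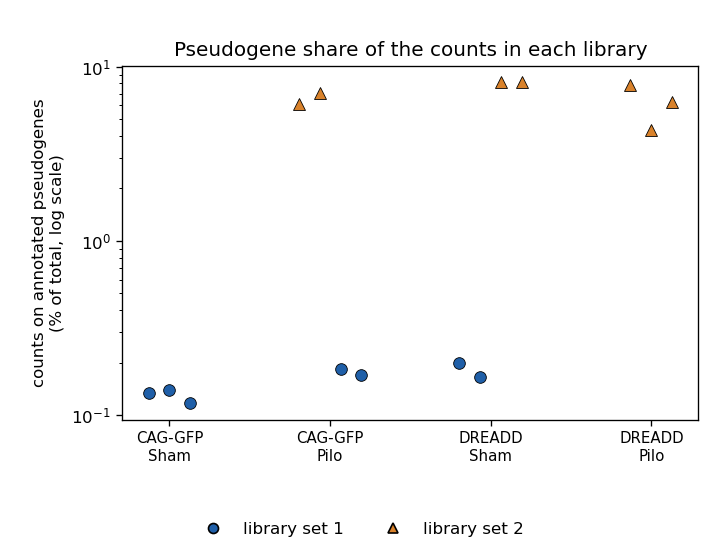
Percent of each library's counts in annotated pseudogenes, by group, on the vertical axis; each point is 1 library, blue circles for set 1 and orange triangles for set 2. Set 1 libraries lie between 0.117% and 0.2%, and set 2 libraries between 4.33% and 8.12%.

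Rrm2 (ENSMUSG00000020649.7), which encodes the small subunit of ribonucleotide reductase, lies on chromosome 12 at 24708241 to 24714146 on the plus strand in the reference annotation used here, GENCODE M21 on GRCm38. Timp3 (ENSMUSG00000020044.9), an inhibitor of metalloproteinases, lies on chromosome 10 at 86300372 to 86349506 on the plus strand. Both are protein-coding genes, and the counts cover each gene's exons as the authors counted them. Rrm2 stood at 4.43 ± 2.34 CPM in CAG-GFP Sham (SD, n = 3), 38.9 ± 40.7 CPM in CAG-GFP Pilo (SD, n = 4), 127 ± 181 CPM in DREADD Sham (SD, n = 4) and 25.8 ± 44 CPM in DREADD Pilo (SD, n = 3). Single libraries moved these Rrm2 means, to 18.5 CPM without CAG-GFP Pilo 4, 40 CPM without DREADD Sham 4 and 0.446 CPM without DREADD Pilo 1. Timp3 stood at 176 ± 3.31, 42.4 ± 23.4, 116 ± 104 and 375 ± 297 CPM in the same groups (SD), with 64.4 CPM in DREADD Sham without library 3 and 235 CPM in DREADD Pilo without library 3.

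All 4 CAG-GFP Pilo libraries lay above all 3 CAG-GFP Sham libraries for Rrm2, and all 4 lay below them for Timp3. The mean log2 difference was 2.31 for Rrm2 and -2.15 for Timp3, each with an exact two-sided permutation p = 0.0286, the smallest that 35 splits allow, and an adjusted p = 0.143 over 10 tests. In the gene-wide edgeR test neither gene passed in this comparison, with log2 fold changes of 3.13 ± 1.90 (SE, adjusted p = 0.42) for Rrm2 and -2.06 ± 0.77 (SE, adjusted p = 0.285) for Timp3. Within library set 1 the fold changes were 3.72 ± 1.87 and -2.40 ± 0.88 (SE), and without CAG-GFP Pilo 4 that of Rrm2 was 2.06 ± 1.86 (SE).

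Between DREADD Pilo and CAG-GFP Pilo, the Timp3 log2 fold change was 3.14 ± 0.79 (SE, adjusted p = 0.882), and Timp3 was the 1 member of the extracellular matrix list past 0.05 when adjusted over the list alone. Within library set 2 it was 2.87 ± 0.90 (SE), and without DREADD Pilo 3 it was 2.46 ± 0.80 (SE). DESeq2 gave an adjusted p = 0.0196 for this difference, and the adjusted p ranged from 0.0196 to 1 over all alternatives. The exact permutation test gave p = 0.0571 (adjusted p = 0.19), with 2 of the 3 DREADD Pilo libraries above every CAG-GFP Pilo library. These were DREADD Pilo 2, at 406 CPM of Timp3, and DREADD Pilo 3, at 656 CPM, while DREADD Pilo 1 held 63.5 CPM. DREADD Pilo 2 also held 2760 CPM of endothelial and 903 CPM of pericyte markers, against 216 and 15.5 CPM in DREADD Pilo 1, and DREADD Pilo 3 held 162000 CPM of ependymal and choroid plexus markers. Rrm2 had a log2 fold change of -0.59 ± 1.71 (SE, adjusted p = 0.996), and within library set 2 the sign turned, to 0.43 ± 1.82 (SE); without CAG-GFP Pilo 4 it was 0.48 ± 1.79 and without DREADD Pilo 1 -6.51 ± 2.22 (SE).

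Neither gene passed the edgeR test in the remaining comparisons. Between DREADD Sham and CAG-GFP Sham, the log2 fold change was 4.84 ± 2.08 for Rrm2 (SE, adjusted p = 0.251) and -0.61 ± 0.76 for Timp3 (SE, adjusted p = 0.758). Within library set 1 these were 0.66 ± 1.78 and -1.72 ± 0.85 (SE). Without DREADD Sham 4 the Rrm2 value was 3.18 ± 1.95 (SE), and without DREADD Sham 3 the Timp3 value was -1.45 ± 0.73 (SE). DESeq2 gave Rrm2 an adjusted p = 0.0209 here, with a range of 0.0209 to 1 over the alternatives. Between DREADD Pilo and DREADD Sham, Rrm2 gave -2.30 ± 1.82 (SE, adjusted p = 1) and Timp3 1.70 ± 0.76 (SE, adjusted p = 0.954), and within library set 2 -3.26 ± 1.84 and 1.08 ± 0.83 (SE). Single libraries moved both, Rrm2 to -0.63 ± 1.80 without DREADD Sham 4 and -8.21 ± 2.40 without DREADD Pilo 1, and Timp3 to 2.54 ± 0.76 without DREADD Sham 3 (SE). The Timp3 fold was also over 1.5 times lower without DREADD Pilo 3. Between DREADD Pilo and CAG-GFP Sham, the values were 2.54 ± 1.91 (SE, adjusted p = 0.518) and 1.09 ± 0.82 (SE, adjusted p = 0.522). These directions did not hold: Rrm2 turned to -3.41 ± 1.94 (SE) without DREADD Pilo 1 and to -1.25 in limma voom, and Timp3 went to 0.35 ± 0.86 (SE) without DREADD Pilo 3 and turned to -0.09 with library set as a covariate. The seizure effect differed between DREADD and CAG-GFP cells by -5.43 ± 2.63 for Rrm2 (SE, adjusted p = 0.429) and 3.75 ± 1.08 for Timp3 (SE, adjusted p = 0.323), on the log2 scale. For Timp3, DESeq2 gave this difference an adjusted p = 0.0315, with a range of 0.0315 to 1. With 1 library left out, the Rrm2 value ran from -11.31 without DREADD Pilo 1 to -3.76 without DREADD Sham 4, and the lowest Timp3 value was 3.10, without DREADD Pilo 3. Without DREADD Sham 3 the Timp3 interaction was larger than pooled, by over 1.5 times as a fold.

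**Figure D2:**
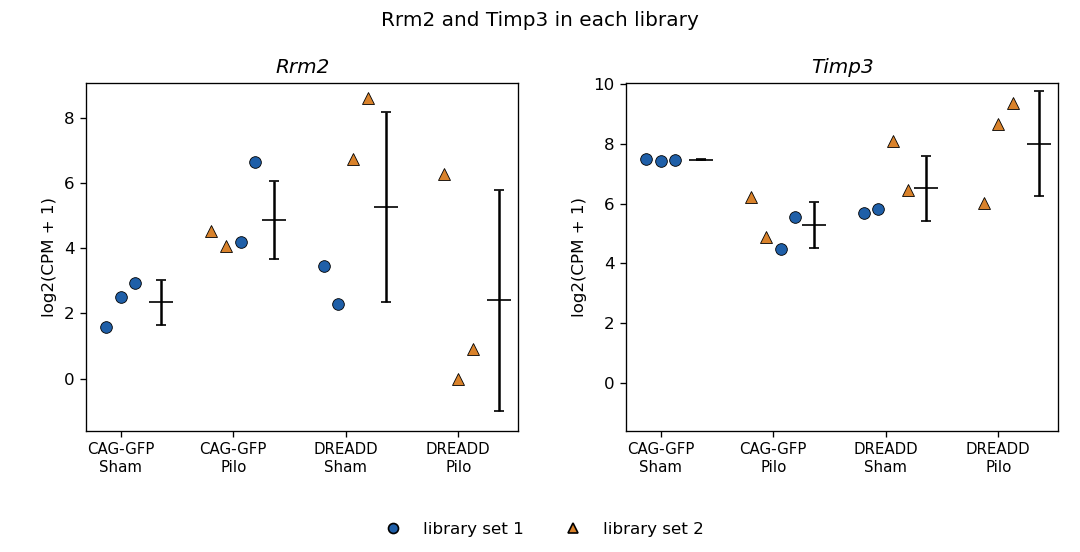
Rrm2 and Timp3 in each library by group, as log2(CPM + 1) on the vertical axis; points are libraries, blue circles for set 1 and orange triangles for set 2, and lines give the mean ± SD per group. For Rrm2 the CAG-GFP Sham libraries lie below the 4 CAG-GFP Pilo libraries, and for Timp3 above them.

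Seizures in CAG-GFP cells were compared first. Astrocyte markers stood lower in CAG-GFP Pilo than in CAG-GFP Sham cells, and oligodendrocyte precursor markers stood higher. The glutathione transferase Gstm1 (ENSMUSG00000058135.8) fell from 8930 ± 564 CPM (SD, n = 3) to 160 ± 54.6 CPM (SD, n = 4), a log2 fold change of -5.80 ± 0.61 (SE, adjusted p = 0.0022). The metallothionein Mt1 fell from 17400 ± 1730 to 608 ± 399 CPM (SD), with a log2 fold change of -4.84 ± 0.77 (SE, adjusted p = 0.0244). Pdgfra (ENSMUSG00000029231.11), the growth factor receptor of oligodendrocyte precursors, rose from 0.341 ± 0.268 to 126 ± 142 CPM (SD), with a log2 fold change of 8.51 ± 1.57 (SE, adjusted p = 0.0386). Without CAG-GFP Pilo 4 its mean there was 61 CPM and its log2 fold change 7.46 ± 1.40 (SE), and without CAG-GFP Sham 3 the change was 9.11 ± 1.98 (SE). Within library set 1 the log2 fold changes were -6.23 ± 0.74 for Gstm1, -6.03 ± 0.81 for Mt1 and 9.03 ± 1.57 for Pdgfra (SE).

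In all, 45 genes passed, 13 higher and 32 lower in CAG-GFP Pilo; with the CAG-GFP Sham libraries summed to 1 sample, 0 passed. Among those with the largest falls were Gstm5 (-6.04 ± 0.99, SE), the phospholipase Pla2g7 (-5.40 ± 0.78), the claudin Cldn10 (-5.62 ± 1.01), Mt2 (-4.63 ± 0.80) and the chaperone clusterin, Clu (-4.56 ± 0.81), on the log2 scale. Hopxos, transcribed antisense to Hopx, fell by 5.35 ± 0.87 (SE) on the log2 scale; whether counting used strand is not stated, so its reads cannot be told from those of Hopx. Gstm1 with Gstm5, Mt1 with Mt2, and Hspa1a with Hspa1b are close relatives whose reads could have been divided between them, so each is uncertain as a separate gene. Among rises, the phosphatase gene Dusp14 went from 2.86 ± 1.84 to 172 ± 32.9 CPM (SD), a log2 fold change of 5.91 ± 0.85 (SE, adjusted p = 0.0167). Lims2 rose by 10.28 ± 1.81 (SE) on the log2 scale, and the heat shock gene Hspa1b rose from 7.49 ± 2.22 to 241 ± 114 CPM (SD, adjusted p = 0.0272). Genes with no count in CAG-GFP Sham were at least 3230-fold higher for the sialidase Neu4, at least 954-fold for Cspg4, an oligodendrocyte precursor proteoglycan, and at least 570-fold for the matrix metalloproteinase Mmp2. These bounds set a group at 0 to 3 counts over the group, and without CAG-GFP Pilo 4 they were 2370, 300 and 363. Dusp26, with 1 count in CAG-GFP Sham, was 5880-fold higher (95% counting interval 1060 to 232000), and Pxdc1, with 2 counts, 936-fold (259 to 7730). Without CAG-GFP Pilo 4 these ratios were 3660 and 486. The CAG-GFP Sham counts of both genes were all in CAG-GFP Sham 2. Without that library the log2 fold change went from 12.13 to 14.21 for Dusp26 and from 9.57 to 12.46 for Pxdc1. Without CAG-GFP Pilo 1 the Cldn10 change was -6.30 ± 1.14 (SE).

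Of the 29 fixed gene lists, 13 passed in this comparison, 9 higher and 4 lower. All 14 astrocyte markers had a negative fold change (median log2 CPM difference -5.07, camera adjusted p = 1.58e-11), and 12 passed when adjusted over the list alone. Acsbg1 was the 1 astrocyte marker past the test over all genes (-3.64 ± 0.67, SE, adjusted p = 0.041), and the glycolytic enzyme Aldoc stood at -3.19 ± 0.70 (SE, adjusted p = 0.0941). All 9 oligodendrocyte precursor markers had a positive fold change (median 7.24, adjusted p = 8.25e-09), with Pdgfra and Cspg4 past the test over all genes and 7 adjusted over the list alone. All 13 oligodendrocyte markers were positive as well (median 3.30, adjusted p = 2.91e-06), and 12 passed adjusted over the list alone; myelin basic protein, Mbp, stood at 56 ± 7.18 and 8470 ± 8960 CPM (SD), with an adjusted p = 0.0946. No list passed in any comparison once the correlation was estimated, and here the adjusted p with an estimated correlation was 0.441 for astrocyte and precursor markers and 0.622 for oligodendrocyte markers.

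The mature granule cell, synaptic vesicle and mitosis lists stood higher in CAG-GFP Pilo, and the neural stem cell list stood lower. In the mature granule cell list 24 of 25 genes were positive (median 2.09, adjusted p = 9.46e-05), and 3 passed adjusted over the list alone. Of these, C1ql2, a secreted synaptic organiser of granule cells, was at least 1120-fold higher (adjusted p = 0.0698 over all genes), and C1ql3 stood at 4.74 ± 0.99 (SE, adjusted p = 0.0698). The synaptic vesicle list (26 of 27 positive, median 1.18, adjusted p = 0.00139) and the mitosis list (28 of 30 positive, median 2.26, adjusted p = 9.46e-05) rose as well, and the vesicle membrane protein gene Vamp2 was among those past 0.05 adjusted over the list alone. CAG-GFP Pilo 3 stood apart, with 6260 CPM of mature granule cell and 8460 CPM of vesicle genes, where the next CAG-GFP Pilo libraries held 2390 and 3560 CPM. Summed interneuron markers were 137 CPM in CAG-GFP Sham and 598 CPM in CAG-GFP Pilo (exact permutation p = 0.143, adjusted p = 0.238), with 1480 CPM in that library. Oxidative phosphorylation genes fell (29 of 32 negative, median -2.19, adjusted p = 2.56e-06), as did cholesterol synthesis genes (18 of 21, median -2.31, adjusted p = 2.9e-05). The neural stem cell list fell (19 of 23 negative, median -2.84, adjusted p = 4.03e-05), led by Fabp7, a fatty acid binding protein of radial glia and astrocytes, at -2.90 ± 0.53 (SE, adjusted p = 0.0386). Cholesterol synthesis had an adjusted p = 0.503 with an estimated correlation, and the others 0.622.

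Neuroblast genes (18 of 22 positive, median 1.42, adjusted p = 0.0198), voltage-gated channels (33 of 35, median 0.97, adjusted p = 0.0307), endothelial markers (13 of 14, median 1.94, adjusted p = 0.0138) and blood cell markers (9 of 9, median 3.03, adjusted p = 0.0447) passed less firmly. Voltage-gated channels had an adjusted p = 0.679 with an estimated correlation, and the other lists 0.622. The neuroblast call ended without CAG-GFP Sham 2 (0.09) or CAG-GFP Pilo 4 (0.0657), the voltage-gated call without CAG-GFP Sham 3 (0.0997) or CAG-GFP Pilo 3 (0.108), the endothelial call without CAG-GFP Pilo 3 (0.0502), and the blood call without CAG-GFP Sham 2 (0.0592), CAG-GFP Pilo 2 (0.0503) or CAG-GFP Pilo 4 (0.419). All 13 lists passed within library set 1, while the mitosis (0.0538), neuroblast (0.0789), endothelial (0.346) and blood calls (0.0789) ended with library set as a covariate. Among the lists that did not pass were S phase genes (adjusted p = 0.066), immediate early genes (0.98), migration and axon guidance (0.1), extracellular matrix (0.0928), interferon (0.932), p53 and stress response (0.948), heat shock (0.948) and ependymal and choroid plexus markers (0.0928).

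The summed astrocyte markers stood at 25100 ± 658 CPM in CAG-GFP Sham (SD, n = 3) and 2740 ± 2350 CPM in CAG-GFP Pilo (SD, n = 4), with an exact permutation p = 0.0286 (adjusted p = 0.114 over 10 cell types). The oligodendrocyte sum was 656 ± 56.4 CPM in CAG-GFP Sham (SD) and 36700, 38700, 1420 and 4440 CPM in CAG-GFP Pilo 1 to 4, so within CAG-GFP Pilo the higher values were those of set 2. The edgeR test called 3 genes without CAG-GFP Sham 1, 2 or 3 or CAG-GFP Pilo 1, each left out in turn, and 8, 9 and 15 without CAG-GFP Pilo 2, 3 and 4. The Gstm1 call held each time, the Mt1 call ended each time (0.0569 to 0.0967), and the Pdgfra call held only without CAG-GFP Pilo 2 (0.0414). DESeq2 called 2203 genes (1713 higher, 490 lower) and limma voom 2020 (789 higher, 1231 lower), and within library set 1 edgeR called 64 genes, of which 32 were among the 45.

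**Figure D3:**
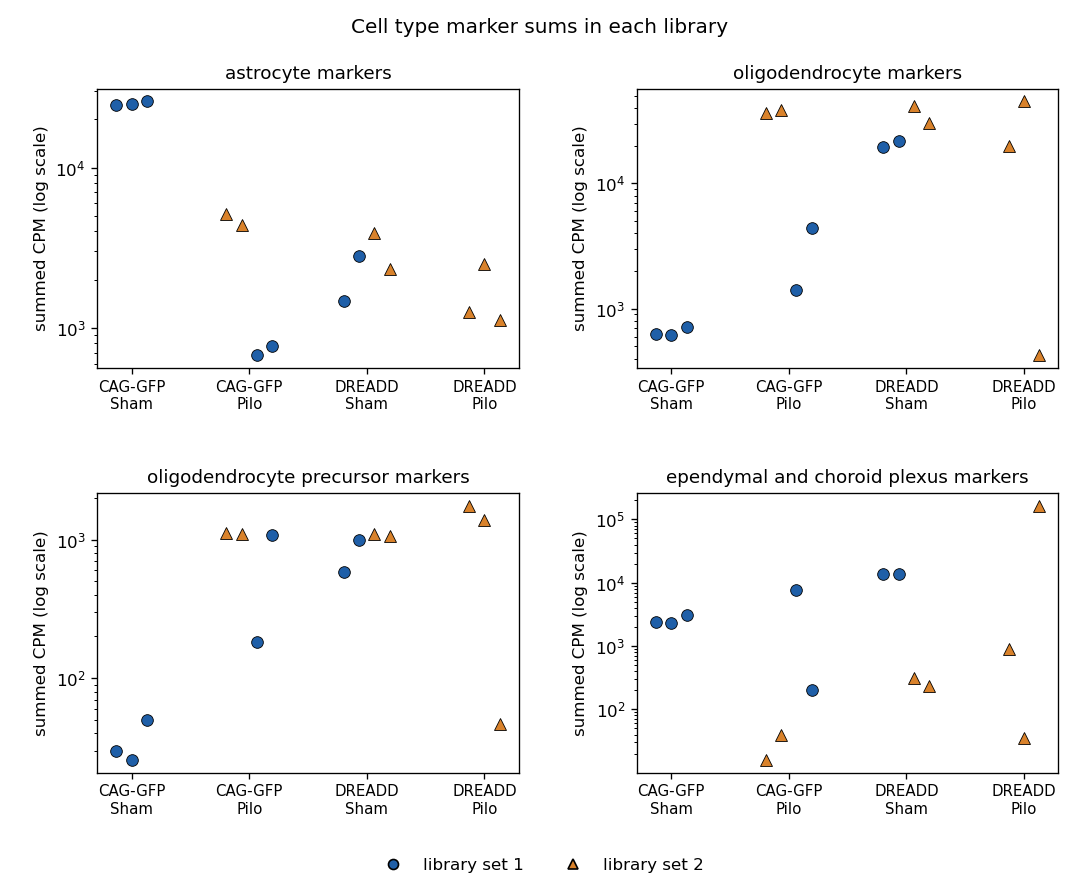
Summed CPM of astrocyte, oligodendrocyte, oligodendrocyte precursor and ependymal and choroid plexus markers per library, on log axes, by group; each point is 1 library, blue circles for set 1 and orange triangles for set 2, with no mean or error drawn. The astrocyte sum is highest in the 3 CAG-GFP Sham libraries, at 25100 ± 658 CPM (SD), and the ependymal and choroid plexus sum is highest in DREADD Pilo 3, at 162000 CPM.

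The effect of the DREADD without seizures was read from DREADD Sham against CAG-GFP Sham. Astrocyte markers stood lower in DREADD Sham cells, and so did several other genes. Carboxypeptidase E, Cpe (ENSMUSG00000037852.7), which trims peptide hormones, fell from 17800 ± 842 CPM (SD, n = 3) to 645 ± 240 CPM (SD, n = 4), a log2 fold change of -4.79 ± 0.65 (SE, adjusted p = 0.00675). The granin Scg3 fell from 2960 ± 15.6 to 123 ± 41.1 CPM (SD), with a log2 fold change of -4.59 ± 0.55 (SE, adjusted p = 0.0061). Pdgfra rose to 229 ± 146 CPM (SD), with a log2 fold change of 9.37 ± 1.62 (SE, adjusted p = 0.0296), or 9.97 ± 2.05 (SE) without CAG-GFP Sham 3. Within library set 1 the log2 fold changes were -4.64 ± 0.59 for Cpe, -4.34 ± 0.61 for Scg3 and 8.31 ± 1.53 for Pdgfra (SE).

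A total of 56 genes passed, 10 higher and 46 lower, and 0 with CAG-GFP Sham summed to 1 sample. Further falls on the log2 scale were Fabp7 (-4.34 ± 0.56, SE), the noncoding RNA Pantr1 (-4.59 ± 0.59), Mt1 (-5.36 ± 0.78), Mt2 (-5.30 ± 0.82), Gstm5 (-5.32 ± 0.96), Cldn10 (-5.18 ± 0.99), the peptide transporter Slc15a2 (-5.49 ± 1.05) and the matrix protein Sparcl1 (-3.76 ± 0.65). The chemokine receptor Ackr3 rose by 8.17 ± 1.51 and Lims2 by 9.21 ± 1.74 (SE) on the log2 scale. Neu4 was at least 2960-fold, Cspg4 at least 1030-fold and Mmp2 at least 329-fold higher, against no count in CAG-GFP Sham. Dusp26 was 6360-fold higher (95% counting interval 1140 to 251000) and Pxdc1 750-fold (208 to 6200). Without CAG-GFP Sham 2 their log2 fold changes went from 12.54 to 14.61 and from 9.47 to 12.36. With 1 DREADD Sham library left out, the lowest bounds were 2680, 750 and 238 and the lowest ratios 5050 and 557. The Ackr3 change was 9.79 ± 1.88 (SE) without CAG-GFP Sham 2 and 7.49 ± 1.47 (SE) without DREADD Sham 3.

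In this comparison 12 lists passed, 8 higher and 4 lower. Oxidative phosphorylation genes fell (31 of 32 negative, median -3.05, camera adjusted p = 2.17e-13), and 12 passed adjusted over the list alone, among them Ndufa2 and Ndufb3 of complex I at -3.29 ± 0.73 (SE, adjusted p = 0.0701) and -2.89 ± 0.70 (SE, adjusted p = 0.102) over all genes. Astrocyte markers fell (14 of 14, median -3.44, adjusted p = 8.55e-09), with Slc4a4 (-3.54 ± 0.67, SE) and Acsbg1 (-3.39 ± 0.67, SE) past the test over all genes and 10 adjusted over the list alone. Cholesterol synthesis genes fell too (16 of 21, median -0.90, adjusted p = 0.0116), as did neural stem cell genes (16 of 23, median -1.90, adjusted p = 0.00556). Oligodendrocyte markers (13 of 13, median 5.09, adjusted p = 9.16e-09) and their precursor markers (9 of 9, median 5.79, adjusted p = 1.78e-07) rose, with 12 and 5 genes past 0.05 adjusted over the list alone; Mbp stood at 7.62 ± 1.65 (SE, adjusted p = 0.0661). With an estimated correlation the adjusted p was 0.57 for oxidative phosphorylation, astrocyte, oligodendrocyte and precursor lists, 0.672 for cholesterol synthesis and 0.693 for neural stem cells.

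Neuroblast genes rose (19 of 22 positive, median 2.25, adjusted p = 0.00055), and 6 passed adjusted over the list alone, among them the transcription factor Neurod1 at 7.67 ± 1.86 (SE, adjusted p = 0.102) and Marcksl1 at 4.79 ± 1.22 (SE, adjusted p = 0.122), or 5.72 ± 1.52 (SE) without CAG-GFP Sham 2. Endothelial markers (14 of 14, median 3.61, adjusted p = 0.00014), pericyte markers (10 of 10, median 2.93, adjusted p = 0.00445), S phase genes (23 of 30, median 1.21, adjusted p = 0.0388), mitosis genes (25 of 30, median 2.26, adjusted p = 0.0303) and mature granule cell genes (22 of 25, median 1.44, adjusted p = 0.049) rose as well. Mitosis and mature granule cells had an adjusted p = 0.849 with an estimated correlation, and the others 0.672. Within library set 1 the mitosis list turned lower (0.77), and the S phase (0.597), endothelial (0.391) and pericyte calls (0.606) ended. Both cell cycle calls ended without DREADD Sham 4, at 0.638 for mitosis and 0.273 for S phase, and without CAG-GFP Sham 2, at 0.095 for each; DREADD Sham 4 held 1270 CPM of mitosis genes in all, against 387 CPM in DREADD Sham 3. The mature granule cell call ended without CAG-GFP Sham 2 (0.057), CAG-GFP Sham 3 (0.094), DREADD Sham 1 (0.352) or DREADD Sham 2 (0.329), and with the size factors of DESeq2 (0.0516). The pericyte call ended without DREADD Sham 4 (0.0521) and the stem cell call without DREADD Sham 1 (0.0519).

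The astrocyte sum in DREADD Sham was 2630 ± 1010 CPM (SD, n = 4), and the oligodendrocyte sum 28200 ± 10100 CPM (SD, n = 4); each gave an exact permutation p = 0.0286 against CAG-GFP Sham (adjusted p = 0.0952). Over all genes, edgeR called 7, 7 and 6 genes without CAG-GFP Sham 1, 2 and 3, and 12, 10, 8 and 8 without DREADD Sham 1 to 4. The Cpe and Scg3 calls held each time, and the Pdgfra call ended each time (0.051 to 0.174). DESeq2 called 2655 genes (2003 higher, 652 lower), limma voom 1909 (720 higher, 1189 lower), and edgeR within library set 1 called 15, of which 12 were among the 56.

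Silenced cells after seizures were also set against cells with neither treatment, DREADD Pilo against CAG-GFP Sham. Heat shock gene Hspa1b stood at 559 ± 490 CPM in DREADD Pilo (SD, n = 3) and 7.49 ± 2.22 CPM in CAG-GFP Sham (SD, n = 3), a log2 fold change of 6.22 ± 0.88 (SE, adjusted p = 0.0139); without DREADD Pilo 1 its mean was 286 CPM and the change 5.19 ± 0.80 (SE). Slc12a2 (ENSMUSG00000024597.10), the chloride importer NKCC1, rose from 17.1 ± 8.96 to 485 ± 398 CPM (SD), with a log2 fold change of 4.83 ± 0.84 (SE, adjusted p = 0.0338). Its highest value, 920 CPM, was in DREADD Pilo 3, the library with 162000 CPM of ependymal and choroid plexus markers, and without that library its mean was 267 CPM and the change 3.90 ± 0.76 (SE). Gstm1 fell to 133 ± 65.6 CPM (SD), with a log2 fold change of -6.07 ± 0.70 (SE, adjusted p = 0.00291). With library set as a covariate the log2 fold changes were 6.29 ± 0.97 for Hspa1b, -6.22 ± 0.75 for Gstm1 and 3.92 ± 0.86 for Slc12a2 (SE), which no longer passed (adjusted p = 0.116).

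Of 42 genes past the test, 12 were higher and 30 lower; here too 0 passed with CAG-GFP Sham summed to 1 sample. Falls on the log2 scale included Gstm5 (-7.43 ± 1.20, SE), Pla2g7 (-6.34 ± 0.92), Cldn10 (-6.48 ± 1.19), Nkain4 (-5.88 ± 1.02), the mitochondrial ribosomal gene Mrps33 (-5.60 ± 1.03), Hopxos (-5.59 ± 0.99), Pantr1 (-5.53 ± 0.70), Fabp7 (-4.58 ± 0.64) and Sparcl1 (-4.12 ± 0.74). Rises included Hspa1a (5.77 ± 1.01, SE), Lims2 (10.27 ± 1.83), Pdgfra (8.68 ± 1.59) and Ackr3 (7.99 ± 1.51). Neu4 was at least 4390-fold, Cspg4 at least 1090-fold and Mmp2 at least 463-fold higher. Dusp26 was 6410-fold higher (95% counting interval 1150 to 253000) and Pxdc1 1620-fold (448 to 13400). Without CAG-GFP Sham 2 their log2 fold changes went from 12.02 to 14.09 and from 10.12 to 13.01. Without DREADD Pilo 1 the bounds for Neu4 and Mmp2 were 1780 and 385 and the Pxdc1 ratio 391, and without DREADD Pilo 2 the Cspg4 bound was 497 and the Dusp26 ratio 4890. Log2 fold changes also moved with single libraries. Without DREADD Pilo 1 they were 8.90 for Lims2 and 4.83 for Hspa1a, and without DREADD Pilo 3 -8.18 for Gstm5 and -6.75 for Hopxos. Without DREADD Pilo 2 they were -7.06 for Pla2g7, -7.21 for Cldn10, -5.27 for Sparcl1 and 7.15 for Ackr3. Ackr3 stood at 9.61 without CAG-GFP Sham 2, and Pdgfra at 9.28 without CAG-GFP Sham 3.

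Here 9 lists passed, 3 higher and 6 lower. Oxidative phosphorylation genes fell (30 of 32 negative, median -2.90, camera adjusted p = 1.34e-14), and 14 passed adjusted over the list alone, among them Sdhb at -4.12 ± 1.12 (SE, adjusted p = 0.148), or -4.91 ± 1.36 (SE) without DREADD Pilo 3. Astrocyte markers fell (14 of 14, median -4.12, adjusted p = 1.37e-11), with Acsbg1 (-5.03 ± 0.81, SE) and Aldoc (-4.62 ± 0.84, SE) past the test over all genes (-5.64 ± 0.98 and -5.23 ± 0.99 without DREADD Pilo 2, SE), and so did cholesterol synthesis genes (20 of 21, median -1.21, adjusted p = 0.000201), where Idi1 stood at -6.11 ± 1.43 (SE, adjusted p = 0.111). Neural stem cell genes (median -1.33), synaptic vesicle genes (median -1.23) and CA pyramidal neuron markers (median -2.63) fell, each with an adjusted p = 0.00652. Endothelial markers (14 of 14, median 5.77, adjusted p = 4.27e-05), oligodendrocyte precursor markers (9 of 9, median 5.82, adjusted p = 0.000445) and oligodendrocyte markers (13 of 13, median 2.99, adjusted p = 0.00198) rose. With an estimated correlation the adjusted p was 0.511 for oxidative phosphorylation, astrocytes, cholesterol synthesis and CA neurons, 0.673 for endothelial and precursor markers, and 0.841 for the others. The vesicle call ended without DREADD Pilo 3 (0.429), the oligodendrocyte call without DREADD Pilo 2 (0.0969) and the stem cell call without DREADD Pilo 1 (0.0543). With library set as a covariate the vesicle (0.908), oligodendrocyte (0.518), endothelial (0.174) and CA neuron calls (0.518) ended.

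The astrocyte sum in DREADD Pilo was 1620 ± 763 CPM (SD, n = 3), with an exact permutation p = 0.1 against CAG-GFP Sham, the smallest that 3 against 3 libraries allow (adjusted p = 0.25). Over all genes, edgeR called 4 genes without CAG-GFP Sham 1, 2 or 3, each left out in turn, 9 and 10 without DREADD Pilo 1 and 2, and 152 without DREADD Pilo 3. The Gstm1 call held each time; the Hspa1b call ended without each CAG-GFP Sham library and the Slc12a2 call without these or DREADD Pilo 2, with largest adjusted p of 0.0977 and 0.203. DESeq2 called 2723 genes (1900 higher, 823 lower) and limma voom 5021 (3099 higher, 1922 lower).

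The 3 comparisons with CAG-GFP Sham shared 26 called genes of a union of 77, among them Acsbg1, Cpe, Cst3, Fabp7, Glul, Gstm1, Mt1, Scg3, Pdgfra and Neu4. Pairs of comparisons shared 31, 30 and 31 genes, every one in the same direction, against at most 0.0084 higher and 0.079 lower genes for independent lists. In 40 simulations of unchanged groups against the same controls, lists of their top genes of the same lengths shared a median of 13, 9.5 and 10. The covariance of fold changes across genes was 3.94, 4.43 and 4.84, against 1.6, 1.59 and 1.59 simulated; r was 0.755, 0.71 and 0.778, against 0.571, 0.535 and 0.534 simulated. CAG-GFP Sham has too few libraries to divide, so part of the excess may come from the shared controls.

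DREADD Pilo against CAG-GFP Pilo asks what silencing changed after seizures. Genes of neurons and synapses stood lower in DREADD Pilo cells, while no gene passed alone. The synaptic vesicle list fell, with 24 of 27 genes negative (median log2 CPM difference -2.42, camera adjusted p = 1.85e-14). The mature granule cell list fell with 23 of 25 negative (median -2.01, adjusted p = 1.67e-07), and its summed level was 3250 ± 2020 CPM in CAG-GFP Pilo (SD, n = 4) and 680 ± 378 CPM in DREADD Pilo (SD, n = 3). CAG-GFP Pilo 3 stood apart, with 6260 CPM of mature granule cell genes and 8460 CPM of vesicle genes, where the next CAG-GFP Pilo libraries held 2390 and 3560 CPM. Summed interneuron markers stood lower as well, at 598 ± 594 and 73.1 ± 28.9 CPM (SD; exact permutation p = 0.0857, adjusted p = 0.381), with 1480 CPM in CAG-GFP Pilo 3. Both lists had an adjusted p = 0.365 with an estimated correlation.

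The edgeR test called 0 genes; 1001 had an unadjusted p under 0.05, where chance gives 934, DESeq2 called 172 (70 higher, 102 lower) and limma voom 11. The genes with the smallest p, all with an adjusted p = 0.882, included Rnf227 at 110 ± 57.1 CPM in CAG-GFP Pilo and 9.85 ± 5.59 CPM in DREADD Pilo (SD), a log2 fold change of -3.48 ± 0.73 (SE), and Slc12a2 at 65.5 ± 33.4 and 485 ± 398 CPM (SD), 2.89 ± 0.69 (SE). Within library set 2 these were -3.69 ± 0.77 and 2.47 ± 0.80 (SE), and without DREADD Pilo 3, which held 920 CPM of Slc12a2, its mean was 267 CPM and its change 2.02 ± 0.67 (SE). Efcab14 stood at 1.93 ± 0.46, Pgbd5 at -3.32 ± 0.80 and the transcription factor Camta1 at -2.42 ± 0.59 (SE). The thiamine transporter gene Slc19a3, with 1 count in CAG-GFP Pilo, had a ratio of 2430 (95% counting interval 436 to 96200). Of its 963 counts in DREADD Pilo, 797 were in DREADD Pilo 2, and without that library the ratio was 659. Slc12a2 passed when adjusted over its list alone.

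Of 13 lists past the test, 12 fell. GABA receptors and chloride transport (16 of 19 negative, median -2.07, adjusted p = 4.98e-06), glutamate receptors (16 of 23, median -0.89, adjusted p = 4.49e-05), late activity-regulated genes (18 of 25, median -1.93, adjusted p = 0.000207), CA pyramidal neuron markers (11 of 12, median -1.87, adjusted p = 0.000563) and oxidative phosphorylation (22 of 32, median -0.98, adjusted p = 1.73e-06) fell in the full data and with any 1 library left out. Glutamate receptors had an adjusted p = 0.423 with an estimated correlation, oxidative phosphorylation 0.646 and the others 0.365. Endothelial markers rose (14 of 14 positive, median 2.81, adjusted p = 0.00417; adjusted p = 0.672 with an estimated correlation), but not without DREADD Pilo 2 (0.307).

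Several calls rested on DREADD Pilo 3, which held 25.8% mitochondrial counts and 162000 CPM of ependymal and choroid plexus markers. Neuroblast genes (16 of 22 negative, median -2.14, adjusted p = 1.73e-06), voltage-gated channels (25 of 35, median -1.33, adjusted p = 5.72e-06) and Gi signalling genes (17 of 27, median -0.97, adjusted p = 0.00846) fell, and without that library their adjusted p was 0.31, 0.0531 and 0.442. Microglia markers (median -0.94, adjusted p = 0.00105) and oligodendrocyte precursor markers (median -1.39, adjusted p = 0.0163) fell by the test, although 13 of 15 and 7 of 9 fitted fold changes were positive; without that library both turned higher, at 0.0911 and 0.287. The precursor call also ended without CAG-GFP Pilo 1 (0.0628) or CAG-GFP Pilo 4 (0.248), and within library set 2 (0.0638). With an estimated correlation the adjusted p was 0.365 for neuroblasts, 0.489 for voltage-gated channels, 0.672 for Gi signalling and precursors and 0.676 for microglia. Within library set 2 the other 12 of these lists passed in the same direction, while with library set as a covariate the oxidative phosphorylation (0.126) and endothelial calls (0.242) ended.

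Whether silencing undid the seizure changes was asked of the 45 genes called between CAG-GFP Pilo and CAG-GFP Sham. Of these, 18 (40%) had a fold change of opposite sign between DREADD Pilo and CAG-GFP Pilo. Simulated unchanged groups with the same shared libraries gave a median of 84.4% (75.6% to 95.6%). The simulations held no seizure change, and their 45 genes were those with the smallest p. Simulated values therefore cannot show whether 40% is low for genes that seizures changed. Over all 18676 genes the share was 58.2%, with r = -0.179 (-0.43 simulated). With the CAG-GFP Pilo libraries divided so that different pairs entered each comparison, the median share for the 45 genes was 41.1% over 6 divisions (33.3% to 57.8%). For the 45 genes with the smallest p in each division, chosen after seeing the data, it was 54.4% (24.4% to 64.4%). Across the 45 genes the fold changes had r = -0.0491 (-0.759 simulated) and a covariance of -0.284 (-13.9 simulated). None of the 45 passed between DREADD Pilo and CAG-GFP Pilo.

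Seizures in DREADD cells were read from DREADD Pilo against DREADD Sham. Neuroblast genes fell, with 21 of 22 negative (median -3.15, camera adjusted p = 4.61e-13), and their summed level was 2650 ± 919 CPM in DREADD Sham (SD, n = 4) and 842 ± 785 CPM in DREADD Pilo (SD, n = 3), where DREADD Pilo 3 held 40.6 CPM. Synaptic vesicle genes fell (24 of 27, median -1.28, adjusted p = 5.64e-07), as did CA pyramidal neuron markers (10 of 12, median -1.35, adjusted p = 0.00172). The adjusted p with an estimated correlation was 0.533, 0.606 and 0.533. These 3 lists held with any 1 library left out, and within library set 2 the neuroblast list held (2.83e-10), while the vesicle (0.15) and CA neuron calls (0.512) ended.

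The edgeR test called 0 genes, with 967 at an unadjusted p under 0.05; DESeq2 called 158 (88 higher, 70 lower), limma voom 6 and edgeR within library set 2 called 5. The smallest p belonged to Hspa1b at 56.1 ± 25.6 CPM in DREADD Sham and 559 ± 490 CPM in DREADD Pilo (SD), a log2 fold change of 3.32 ± 0.69 (SE, adjusted p = 0.954), or 3.48 ± 0.90 (SE) within library set 2 and 2.32 ± 0.66 (SE) without DREADD Pilo 1. With the same adjusted p, Vamp8 stood at 2.96 ± 0.72, the isoprenoid enzyme Idi1 at -5.12 ± 1.34, Rnf227 at -2.62 ± 0.70 and Tns3 at 2.83 ± 0.77 (SE). Without DREADD Pilo 3 the Vamp8 mean in DREADD Pilo went from 542 to 154 CPM and its change to 1.12 ± 0.51 (SE). Without DREADD Sham 2 the Idi1 mean in DREADD Sham went from 122 to 46.8 CPM and its change to -3.74 ± 1.15 (SE), and without DREADD Pilo 1 Rnf227 stood at -3.21 ± 0.85 (SE). Slc19a3, with 1 count in DREADD Sham, had a ratio of 2350 (95% counting interval 421 to 93000), or 637 without DREADD Pilo 2.

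A further 11 lists passed, each losing its call without at least 1 library. Mature granule cell (adjusted p = 0.000919), glutamate receptor (0.00097), voltage-gated channel (0.000344) and GABA receptor genes (0.00684) fell, and without DREADD Pilo 3 gave 0.0781, 0.411, 0.387 and 0.387; the GABA call also ended without DREADD Sham 1 (0.123). All 4 calls ended within library set 2, where the mature granule cell list turned higher (0.675). Oligodendrocyte (0.000919) and precursor markers (0.0269) fell by the test with 8 of 13 and 7 of 9 fitted fold changes positive, and turned higher without DREADD Pilo 3 (0.665 and 0.156); the precursor call also ended without DREADD Sham 3 (0.079) or DREADD Sham 4 (0.126). Pericyte markers fell (0.00888), but not without DREADD Sham 3 (0.13), DREADD Sham 4 (0.19) or DREADD Pilo 1 (0.563), and astrocyte markers fell (0.011), but not without DREADD Sham 3 (0.079), DREADD Pilo 1 (0.116) or DREADD Pilo 3 (0.0781). S phase genes fell (0.0383), but not without DREADD Sham 3 (0.079), DREADD Sham 4 (0.604), DREADD Pilo 2 (0.285) or DREADD Pilo 3 (0.156). Cholesterol synthesis genes fell (0.0269), but not without DREADD Sham 2 (0.0676), DREADD Sham 4 (0.0558) or DREADD Pilo 1 (0.139), nor within library set 2 (0.151). Interferon genes rose (21 of 25 positive, median 1.07, adjusted p = 0.0269), but not without DREADD Sham 2 (0.307), DREADD Sham 4 (0.126), DREADD Pilo 1 (0.287) or DREADD Pilo 2 (0.476). Summed microglia markers moved with them, at 6740 ± 5030 CPM in DREADD Sham and 17100 ± 17100 CPM in DREADD Pilo (SD; exact permutation p = 0.343, adjusted p = 0.619). Both sums were lowest within DREADD Pilo in DREADD Pilo 3, at 1470 CPM of interferon genes and 235 CPM of microglia markers. Each of the 11 had an adjusted p = 0.606 with an estimated correlation.

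The interaction asks whether seizures acted differently in DREADD and CAG-GFP cells. Its sign rests on both sham groups, and for glial lists CAG-GFP Sham stood apart by group means. Summed oligodendrocyte markers were 656 CPM in CAG-GFP Sham and 20300, 28200 and 21800 CPM in CAG-GFP Pilo, DREADD Sham and DREADD Pilo. Precursor markers were 35.3 against 866, 930 and 1060 CPM, and astrocyte markers 25100 against 2740, 2630 and 1620 CPM. By library, DREADD Pilo ran from 426 to 45000 CPM of oligodendrocyte and from 46.9 to 1740 CPM of precursor markers. CAG-GFP Sham ran from 623 to 721 and from 25.8 to 50.1 CPM, so the lowest DREADD Pilo values were no higher than those of CAG-GFP Sham. For the glial lists the CAG-GFP Sham level therefore enters the interaction, and for oligodendrocyte and precursor markers low DREADD Pilo values enter it too. Both of these lists also fell by the test between DREADD Pilo and DREADD Sham (camera adjusted p = 0.000919 and 0.0269). They turned higher there without the DREADD Pilo library that held the lowest values. For the glial lists the interaction does not by itself show a different response to seizures. The interaction was negative for 21 of 22 neuroblast genes and for all 9 oligodendrocyte precursor markers (camera adjusted p = 4.31e-10 each), for 13 of 13 oligodendrocyte markers (4.01e-09), 26 of 27 synaptic vesicle genes (1.25e-08) and 24 of 25 mature granule cell genes (8.51e-08). It was positive for all 14 astrocyte markers (5.87e-06). Each of these had an adjusted p = 0.441 with an estimated correlation.

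In all 16 lists passed, 12 lower and 4 higher, and each also passed with library set as a covariate. These 6, with voltage-gated channels (34 of 35 negative, 3.27e-05), GABA receptors (0.00131), neural stem cells (19 of 23 positive, 0.00131) and S phase genes (0.00342), held with any 1 library left out. Their adjusted p with an estimated correlation was 0.51 for voltage-gated channels and stem cells and 0.441 for GABA receptors and S phase genes. The mitosis call (27 of 30 negative, 0.00131) ended without DREADD Sham 4 (0.0837), and without DREADD Pilo 3 the oxidative phosphorylation call (23 of 32 positive, 0.00231) gave 0.133 and the glutamate receptor call (0.00342) 0.0556. With an estimated correlation the adjusted p was 0.51 for mitosis and glutamate receptors and 0.614 for oxidative phosphorylation. The interneuron call (0.0171, or an adjusted p = 0.441 with an estimated correlation) ended without CAG-GFP Pilo 2 (0.0668) or DREADD Pilo 3 (0.0556). The blood cell call (0.0265, or an adjusted p = 0.51 with an estimated correlation) ended without CAG-GFP Pilo 4 (0.143), DREADD Sham 1 (0.0685), DREADD Sham 3 (0.0782), DREADD Pilo 1 (0.123) or DREADD Pilo 3 (0.284). The cholesterol call (0.0353, or an adjusted p = 0.51 with an estimated correlation) ended without CAG-GFP Sham 1 (0.0589), CAG-GFP Sham 3 (0.0526), CAG-GFP Pilo 3 (0.0703), DREADD Sham 3 (0.0793), DREADD Sham 4 (0.0518) or DREADD Pilo 3 (0.0556).

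The edgeR test called 0 genes for the interaction, with 2191 at an unadjusted p under 0.05; DESeq2 called 1461 (301 higher, 1160 lower), limma voom 185 and edgeR without DREADD Pilo 3 called 1. The smallest p belonged to genes with an adjusted p = 0.194. Among them the protease inhibitor Cst3 stood at 93000 ± 10600, 11400 ± 4500, 5090 ± 1710 and 11800 ± 4250 CPM in CAG-GFP Sham, CAG-GFP Pilo, DREADD Sham and DREADD Pilo (SD), an interaction of 4.24 ± 0.70 (SE) on the log2 scale. Dusp14 gave -5.80 ± 1.03, Naaa 5.07 ± 0.91 (4.06 ± 0.81 without DREADD Pilo 3) and Gstm1 4.17 ± 0.75 (SE); Dusp26 and Neu4 were also in this group, with 1 and 0 counts in CAG-GFP Sham. Mbp gave -8.49 ± 1.98 (SE, adjusted p = 0.219), Neurod1 -9.77 ± 2.29 (SE, adjusted p = 0.219) and the vesicle GTPase Rab3a -3.61 ± 0.98 (SE, adjusted p = 0.288). With 1 library left out, Mbp moved to -7.90 without CAG-GFP Pilo 2, -9.29 without DREADD Pilo 2 and -7.87 without DREADD Pilo 3, and Neurod1 to -9.07 without CAG-GFP Pilo 2 and -9.14 without DREADD Pilo 3.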

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

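The tests of library sets, astrocyte RNA, other cell types, pseudogenes, depth and choroid plexus in this part were chosen after the results were seen, while the splice junction test and the counts of other splits were written before. Among other splits of the same libraries, 1 of 35, the real one, called as many genes as the 45 of CAG-GFP Pilo against CAG-GFP Sham, and 1 of 35 as many as the 56 of DREADD Sham against CAG-GFP Sham. The highest of the other splits was 0 in each. Both counts rest on the same CAG-GFP Sham libraries, which resembled each other closely, and no label states that these are independent. Other splits mix them with less alike libraries, which raises the spread within groups. The splits thus set the CAG-GFP Sham libraries apart from the rest, but cannot exclude chance for an effect of treatment. Summed to 1 sample, the CAG-GFP Sham libraries left no spread within that group, and the calls in both comparisons did not hold. For DREADD Pilo against CAG-GFP Sham, 1 of 10 splits, the real one, gave 42 genes and the highest other gave 1, but 10 splits are too few for a share under 0.05. Where the real comparison called 0 genes, every split is as large by construction, so chance cannot be excluded. This was 35 of 35 splits for DREADD Pilo against CAG-GFP Pilo (highest other 1), 35 of 35 for DREADD Pilo against DREADD Sham (highest other 5) and 100 of 100 drawn for the interaction. The highest other interaction split called 104 genes, with CAG-GFP Pilo 1 and 2 and DREADD Pilo 3 in the place of the DREADD Pilo group. These are all of library set 2, as are the real DREADD Pilo libraries. The libraries in the place of the other groups were not examined, so whether library set explains the 104 calls is not settled. With library set as a covariate the interaction called 11.

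The genes called against CAG-GFP Sham were the first pattern weighed. Within set 1 alone edgeR called 64 and 15 genes in the CAG-GFP Pilo and DREADD Sham comparisons, where no set difference enters. This argues against a difference between library sets as the whole cause there. The genes called in the pooled data had median signed log2 changes of 4.82 and 3.72 within set 1, against 4.44 and 4.05 pooled. These genes were chosen with the same libraries and did not overlap between the groups, so the medians are no separate evidence. For DREADD Pilo, 0 sets hold both groups, so set and group cannot be told apart. More of every other cell type in CAG-GFP Sham is argued against too, since 2 of 10 marker sums were highest there, those of astrocytes and, with TMM factors but not with plain CPM, CA pyramidal neurons. More astrocyte RNA in CAG-GFP Sham, from astrocytes or their RNA passing the GFP sort, remains a candidate explanation for the falls, since 14 of 14 astrocyte markers had their highest group mean there and the lowest CAG-GFP Sham library lay above every other library for 14, with Aldoc at 8350 ± 335 CPM (SD). A biological effect of seizures or of the DREADD on these cells remains open and untested.

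The 2 sets of libraries were the second pattern, with 1639 genes called between them, 927 higher and 712 lower in set 2. A difference in total counts is argued against as the whole cause, since 1560 of these genes were still called with the libraries thinned to equal totals. Reads moved to pseudogenes fit the values: pseudogenes made up 82.1% of the annotated genes called higher in set 2 and 6.62% of all, and 64 of 77 ribosomal protein genes were lower. Reads placed differently at splice junctions may also play a part, since the fold change in set 2 fell with the number of junctions per kb (Spearman rho -0.188 over 14653 protein-coding genes, interval -0.204 to -0.171; genes are not independent replicates). No biological explanation was tested, since the sets cross the groups.

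The third pattern was a choroid plexus signal in DREADD Pilo 3. A single abundant transcript is argued against, since 9 of the 10 markers besides Ttr were also highest in that library, although Ttr made up 92.8% of its marker sum. Choroid plexus cells or their RNA remain a candidate explanation: 10 of 11 markers were highest there, all but Rarres2, with Ttr at 150000 CPM against 13400 CPM in the next library, Kcnj13 at 5640 against 283, Kl at 2790 against 52.7 and Clic6 at 1600 against 51.6. The GFP sort would remove such cells unless they carried GFP or came with their RNA alone. No biological explanation was tested.

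In groups of 4 libraries, 23 of 232 tested values had 1 library far from the others (gap over range above 0.829). For normally distributed values chance gives about 1 in 20, or 11.6. The values were mostly CPM without a log scale, which can be skewed, and they share libraries. The 23 therefore do not show an excess over chance. In CAG-GFP Pilo 3 the list sums, with the nearest other library in parentheses, were 6260 CPM for mature granule cells (2390), 8460 for synaptic vesicles (3560), 183 for oligodendrocyte precursors (1070), 1480 for interneurons (392), 482 for CA pyramidal neurons (229) and 7690 for ependyma and choroid plexus (200). Other list sums set apart were blood cells at 18600 CPM in CAG-GFP Pilo 4 (1220), S phase genes at 1530 in DREADD Sham 4 (525) and voltage-gated channels at 1340 in DREADD Sham 1 (630). Single genes set apart in CAG-GFP Pilo 3 were Ndufa2 at 212 CPM (241), Vtn at 6.98 (0), Ly6c1 at 96.5 (9.4), Flt1 at 10.9 (1.47) and Slc19a3 at 0.0247 (0). In other CAG-GFP Pilo libraries these were Cspg4 at 147 in library 4 (20), Rrm2 at 99.8 in library 4 (22.4), Hspa1a at 208 in library 1 (122) and Erbb4 at 15.2 in library 2 (2.44). In DREADD Sham 3 these were Timp3 at 270 (86), Efcab14 at 177 (122) and Slc12a2 at 251 (113), and in DREADD Sham 2 Lims2 at 264 (117) and Slc19a3 at 0.0325 (0).

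The interaction of seizures with the DREADD passed in 16 lists by the test with the preset correlation, while 0 lists passed with an estimated correlation. The CAG-GFP Sham level enters this for every list, and plainly for the astrocyte, oligodendrocyte and precursor lists. Their mean sums were 25100, 656 and 35.3 CPM there against 1620 to 2740, 20300 to 28200 and 866 to 1060 CPM in the other groups. Single DREADD Pilo libraries went down to 426 CPM of oligodendrocyte and 46.9 CPM of precursor markers, so that group enters it too. The adjusted p was 4.31e-10 for neuroblasts and for oligodendrocyte precursors, 4.01e-09 for oligodendrocytes, 1.25e-08 for synaptic vesicles, 8.51e-08 for mature granule cells, 5.87e-06 for astrocytes and 3.27e-05 for voltage-gated channels. It was 0.00131 for mitosis, neural stem cells and GABA receptors, 0.00231 for oxidative phosphorylation, 0.00342 for S phase and glutamate receptors, 0.0171 for interneurons, 0.0265 for blood cells and 0.0353 for cholesterol synthesis.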

How the results depend on the processing

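Library set as a covariate, comparison within 1 set, CAG-GFP Pilo 4 with DREADD Pilo 3 left out, CAG-GFP Sham summed to 1 sample and the lists under other size factors were chosen after the results were seen; the other alternatives were planned. Counts below are genes past the threshold, against 45 for CAG-GFP Pilo and CAG-GFP Sham, 56 for DREADD Sham and CAG-GFP Sham, 42 for DREADD Pilo and CAG-GFP Sham, and 0 by edgeR for DREADD Pilo against CAG-GFP Pilo, DREADD Pilo against DREADD Sham and the interaction, where 1001, 967 and 2191 genes had an unadjusted p under 0.05. In this order DESeq2 called 2203, 2655, 2723, 172, 158 and 1461 genes, and limma voom 2020, 1909, 5021, 11, 6 and 185. Of the 45, 56 and 42 genes, DESeq2 called 44, 55 and 42, and limma voom 45, 56 and 42.

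With only the compared groups, edgeR called 168, 647 and 2407 genes in the 3 comparisons with CAG-GFP Sham, and at a threshold of 0.10 it called 103, 154 and 98. With the naming style as a covariate it called 25, 106 and 18, with library set as a covariate 89, 146 and 40, and with CAG-GFP Pilo 4 and DREADD Pilo 3 left out 216, 579 and 357. With CAG-GFP Sham summed to 1 sample the calls did not hold. That group then had no spread of its own, and the lone sample was assumed to vary like the other groups. Fewer samples may account for this, since edgeR called 3, 6 or 7, and 4 genes with any 1 CAG-GFP Sham library left out. The rise with CAG-GFP Pilo 4 and DREADD Pilo 3 left out does not exclude it. Those libraries stood apart from their groups, and the CAG-GFP Sham libraries resembled each other. For DREADD Sham against CAG-GFP Sham, upper-quartile factors gave 86, the strict filter 118 and set 1 alone 15. For CAG-GFP Pilo against CAG-GFP Sham, 8 genes were called without CAG-GFP Pilo 1 and 2, and 27 without CAG-GFP Pilo 3 and 4. For DREADD Pilo against DREADD Sham, library set as a covariate gave 2 genes and set 2 alone 5; for the interaction, library set as a covariate gave 11 and no filter 3.

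With 1 library left out, the 3 comparisons with CAG-GFP Sham called 3 to 15, 6 to 12 and 4 to 152 genes, DREADD Pilo against CAG-GFP Pilo or DREADD Sham 0, and the interaction 0 to 1. The cause of each change was not tested, except that leaving out libraries leaves fewer samples. For gene lists, the estimated correlation gave 0 in each of the 6 comparisons. With 1 library left out, 11 to 15 lists passed for CAG-GFP Pilo and CAG-GFP Sham, 9 to 14 for DREADD Sham and CAG-GFP Sham, 9 to 15 for DREADD Pilo and CAG-GFP Sham, 11 to 20 for DREADD Pilo and CAG-GFP Pilo, 9 to 16 for DREADD Pilo and DREADD Sham, and 12 to 23 for the interaction. The 15 and a value of 14 came without DREADD Pilo 1 and 2, the 20 without DREADD Pilo 1 and the 9 without DREADD Pilo 3. Other size factors turned no list; they ended the mature granule cell call between the sham groups (0.0516) and added late activity-regulated genes in the interaction (0.0489) and mitosis in DREADD Pilo against CAG-GFP Sham (0.0286).

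The labels give the groups the same replicate numbers. With the replicate block edgeR called 1, 0 and 9 genes in the 3 comparisons with CAG-GFP Sham, and 0 in the others. Libraries of the same number correlated at -0.381 to 0.115 over 19 pairs, and 1 of 14 libraries correlated best with its own number. Many of these pairs cross library sets, among them every such pair of CAG-GFP Pilo with DREADD Sham, so this check could miss pairing. The numbers were not read as pairs because no label states that they pair animals.

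Of 4190 values of 184 named results under the alternatives, 3266 kept direction and side of the threshold, 541 were no longer past it, 375 were newly past it and 8 turned. Only results past the threshold could lose their call, so the 541 fall on these alone and are not to be read as a share of the 4190. Of the 541, 314 came with 1 library left out. Many calls ended whichever library was left out, such as Mt1 and Pla2g7 between CAG-GFP Pilo and CAG-GFP Sham, while that of Gstm1 held each time. The 3266 include results that were not past the threshold and stayed so, and all 184 values of the setting with a log2 change of at least 1. Rrm2 between DREADD Pilo and CAG-GFP Pilo turned from -0.59 to 0.43 with the naming style as a covariate and within set 2, to 0.44 without CAG-GFP Pilo 3 and 4, to 0.48 without CAG-GFP Pilo 4 (range with 1 library left out -6.51 to 0.48) and to 1.04 without CAG-GFP Pilo 4 and DREADD Pilo 3. Rrm2 between DREADD Pilo and CAG-GFP Sham turned from 2.54 to -1.25 in limma voom and to -3.41 without DREADD Pilo 1 (range with 1 library left out -3.41 to 3.07), and Timp3 there from 1.09 to -0.09 with library set as a covariate. The marker sums passed in no comparison, also with plain CPM, but the exact permutation test had little room to pass. Its smallest p was 0.1 with 3 against 3 libraries, where no sum could pass. With 4 against 3 it was 0.0286, so after adjustment several lists had to reach it together. The lack of a pass therefore does not show that the sums were alike. The median log2 fold change of all genes was 0.409 for CAG-GFP Pilo against CAG-GFP Sham with TMM, 0.443 with DESeq2 size factors and 0.251 with upper-quartile factors; it was 0.527, 0.618 and 0.337 for DREADD Sham and 0.665, 0.812 and 0.456 for DREADD Pilo against CAG-GFP Sham. It was 0.28, 0.384 and 0.242 for DREADD Pilo against CAG-GFP Pilo and -0.432, -0.409 and -0.303 for the interaction, so fold changes read relative to these medians.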

Other observations

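The tests in this part were all chosen after the results were seen, apart from the edgeR values of named genes. Heat shock gene Hspa1b stood at 7.49 ± 2.22 CPM in CAG-GFP Sham (SD, n = 3), 56.1 ± 25.6 CPM in DREADD Sham (SD, n = 4), 241 ± 114 CPM in CAG-GFP Pilo (SD, n = 4) and 559 ± 490 CPM in DREADD Pilo (SD, n = 3). Its reads could have been divided with those of Hspa1a, a close relative. The mitochondrial chaperonin Hspe1 of the same list stood at -2.61 ± 0.74 in CAG-GFP Pilo (SE, adjusted p = 0.209) and -3.16 ± 0.75 in DREADD Sham (SE, adjusted p = 0.0979) against CAG-GFP Sham, on the log2 scale. Among activity-regulated and stress genes, Arc stood at 8.28 ± 2.34 in DREADD Sham (SE, adjusted p = 0.148) and Gadd45g at -2.51 ± 0.67 (SE, adjusted p = 0.129), while Atf4 and Atf3, transcription factors of the stress response, stood at 2.69 ± 0.69 (SE, adjusted p = 0.134) and 2.77 ± 0.77 (SE, adjusted p = 0.152) in DREADD Pilo against CAG-GFP Sham. Single libraries moved some of these values. Arc stood at 12.43 ± 3.22 and Atf4 at 3.28 ± 0.83 without CAG-GFP Sham 3, and Hspe1 at -3.84 ± 0.80 in DREADD Sham without DREADD Sham 2 (SE). Without DREADD Pilo 1 the Hspa1b mean there was 286 CPM.

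Rrm2 acts in DNA synthesis, so its level may follow that of mitosis genes across libraries. Within library set 1 Pearson's r was 0.335 over 7 libraries (permutation p = 0.361, adjusted p = 0.361 over 2 relations), Spearman's rho 0.5 (permutation p = 0.267), and r without the 2 libraries farthest from the median 0.419. Within set 2 r was 0.729 over 7 libraries (permutation p = 0.053, adjusted p = 0.106), rho 0.536 (permutation p = 0.236), and r without 2 libraries 0.324. Neither relation passed, so the hypothesis stays undecided.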
